A study of Mus musculus with 70 samples.

How the data were processed

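The submitters' processing notes name STAR 2.4.2a for alignment to the mouse genome mm10, Subread and featureCounts 1.4.6 for counting and DESeq2 for testing. Libraries were made from rRNA-depleted total RNA and read as single 50 nt reads, from samples with an RNA integrity number above 6.5. The gene annotation they counted against is not given in the sources used here. The tables held RPKM, reads scaled to gene length and library total, as the deposited table names state. The workbook of the authors' tests held log2 fold changes with standard errors per the file headers. Its adjusted p-value columns also came from the authors' DESeq2 tests. The time of each ulna table came only from the names of workbook sheets. Each stress fracture contrast computed here correlated best with the authors' table of its own time, with r across genes from 0.966 to 0.996 against at most 0.925 for another time, and genes are not independent replicates. The time labels call the samples periosteum, whereas the protocol describes whole bone sections. The series text counts 70 mice, whereas the sample titles carry 50 animal numbers.

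The 10 tables of RPKM, 5 per bone, were read with all 67 library columns. Intact columns repeated in the 5 tables of a bone were the same, with a largest difference of 4.22e-06 RPKM in femurs and 0 in ulnas. There were 47517 gene names in the femur and 46882 in the ulna tables, of which 45634 names were shared. In each bone 27 gene names had been turned into dates by a spreadsheet and were left out, with 0.106% of the femur and 0.105% of the ulna RPKM. Depth was recovered as the number of assigned reads that makes small values whole reads, with gene lengths of GENCODE M21, and from 88.7% to 91.3% of values under 20 reads were then whole within 0.01. Gene positions are those of M21 on GRCm38 (mm10). Reads of near-identical copies (Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, Bglap and Bglap2, Hspa1a and Hspa1b) are hard to assign, so values of single copies are uncertain.

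RPKM were scaled by the median of ratios to the geometric mean over genes above 0 in every library, with factors from 0.835 to 1.14 in femurs, from 0.905 to 1.11 in ulnas and from 0.782 to 1.18 in both bones together. Genes with at least 0.5 scaled RPKM in at least 5 libraries were kept, 19944 in femurs, 20506 in ulnas and 21092 in both. Log2 of scaled RPKM plus 0.1 was fitted with limma 3.58.1 in R 4.3.3, with a trend of variance on mean and robust variance estimates, and p-values were adjusted by Benjamini and Hochberg over all genes of a contrast at 0.05. The added 0.1 holds down folds of genes near 0. Femur libraries formed 1 fit, ulna libraries another, and a fit of all 67 gave the difference between injuries (injured minus intact femur, minus injured minus intact ulna) and intact ulna minus intact femur. RPKM as deposited, used as an alternative, differ from the scaled values by 1 factor per library. Libraries of a group correlated with r from 0.898 to 0.961 on the log2 scale.

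Before the data were examined, 33 lists of 384 distinct genes were fixed, some genes standing in more than 1 list. They covered immediate early genes, inflammatory cytokines and chemokines, heat shock genes, interferon response genes, cell cycle genes, glycolysis and hypoxia genes, oxidative phosphorylation genes, angiogenic factors, BMP and TGF-beta ligands and antagonists, Wnt ligands, targets and antagonists, fibrous matrix genes, matrix proteases and inhibitors and a fracture repair panel. Cell type lists covered neutrophils, macrophages, T cells, B cells, erythroid cells, platelets and megakaryocytes, mast cells, skeletal muscle, muscle regeneration, adipocytes, tendon, Schwann cells, keratinocytes, mesenchymal progenitors, chondrocytes, hypertrophic chondrocytes, osteoblasts, osteocytes, osteoclasts and endothelium. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a contrast, with an estimated correlation beside it. Camera called 239 lists over the 15 contrasts, of which 13 held with an estimated correlation. List tests of intact ulna against intact femur were added to the plan, and the list results given in the text were chosen after the results were seen. Values of 3 single genes are not reported here. Named genes followed a rule fixed in advance. For each injury contrast it took the 3 largest rises and falls with adjusted p under 0.05, at least 5 scaled RPKM in the higher group and no overlap of injured and intact libraries. For differences and intact limbs it took the 4 largest each way, and list members and panel genes could be named besides.

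A self-test simulated RPKM of unchanged genes with known changes added to some. At a log2 change of 1, calls recovered 76.9% of the genes in the femur fit, 79.4% in the ulna fit and 66.2% in the difference, with false calls of 3.27%, 7.27% and 5.84%. At a log2 change of 0.5 the shares were 38.7%, 47.7% and 29.5%, so many small changes were missed in the simulation. There the noise of genes was independent, and 153 of 19142 genes were called in the femur fit. At 7 d after full fracture 13195 of 19944 genes were called, so the simulated shares do not carry over to such contrasts. Scaling with many changed genes was not tested by the simulation. In the authors' deposited tests 10046, 10004, 10883, 12003 and 10800 genes changed at 4 h, 1 d, 3 d, 7 d and 14 d after full fracture, and 2871, 3313, 8186, 8981 and 7704 at 4 h, 1 d, 3 d, 5 d and 7 d after stress fracture. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.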

Results

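Bone RNA was sequenced from 12-week-old female C57BL/6 mice after 1 of 2 injuries. The femur received a full fracture, a break through the whole bone that heals through a cartilage callus (endochondral ossification). The ulna received a stress fracture, a partial crack that heals mostly by bone laid down directly (intramembranous ossification). Femurs were taken 4 h, 1 d, 3 d, 7 d and 14 d after full fracture and ulnas 4 h, 1 d, 3 d, 5 d and 7 d after stress fracture. The uninjured left limbs were the intact controls. Each femur gave a 7 mm section from which marrow was spun out, and each ulna a 5 mm section for which no such step is named in the protocol. The tables held 67 libraries. There were 10 intact femurs, 5 femurs at each time after full fracture, 9 intact ulnas, 5 ulnas at 4 h, 3 d and 5 d after stress fracture and 4 ulnas at 1 d and 7 d. Another 3 samples of the labels, an intact ulna and 1 each at 1 d and 7 d after stress fracture, were not analysed here.

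Reads assigned to genes, recovered from the steps of the deposited RPKM, ran from 8.12 to 30.8 M per library with a median of 16.4 M. Intact ulnas had 13.4 ± 2.91 M (SD, n = 9) and femurs at 7 d after full fracture 21.3 ± 5.64 M (SD, n = 5), the lowest and highest group means. Changes below are log2 differences from the intact limbs of the same bone with the standard error of the limma fit, and group levels are scaled RPKM with their SD. A list score is the mean log2 difference of a library's list members from the intact libraries. List counts are adjusted over all genes tested, and where no other count is given that adjusted over the list alone was the same. The labels did not tie table columns to animals, so each library was treated as 1 independent sample and p-values measure the spread between samples. That independence does not hold for all libraries. By animal number the intact limbs were the other limbs of injured animals, 10 pairs per bone in the labels. An effect of the injury on the other limb was not tested. Counts of changed genes at each time are plotted against intact limbs for both injuries.

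**Figure D1:**
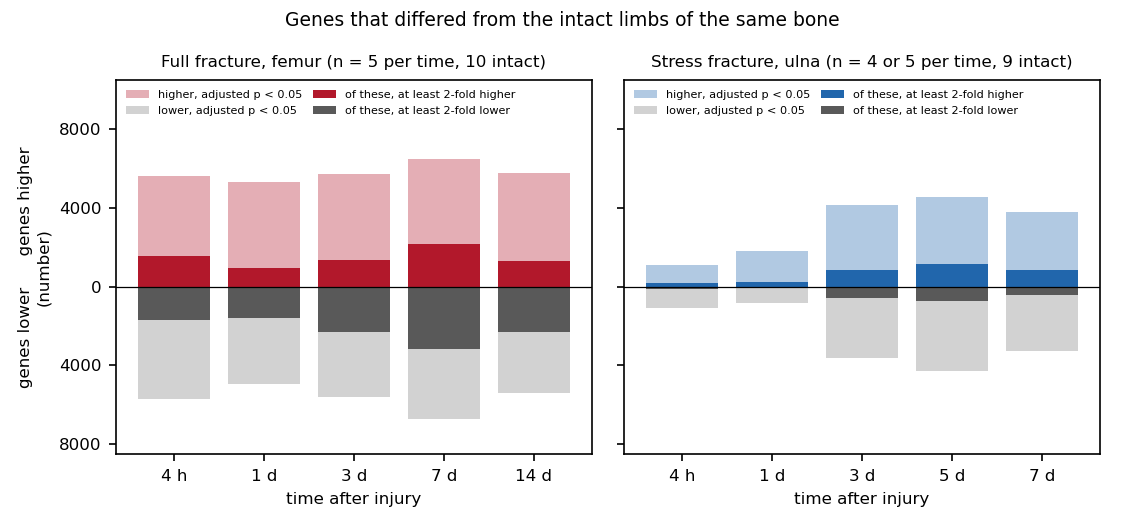
Number of genes higher (above 0) or lower (below 0) than in intact limbs at adjusted p < 0.05, by time after full fracture (left, 5 femurs per time against 10 intact) and stress fracture (right, 4 or 5 ulnas per time against 9 intact), with the darker part of each bar for changes of at least 2-fold. Full fracture changed from 10270 to 13195 genes at each time, and stress fracture from 2193 genes at 4 h to 8873 at 5 d.

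Each time after full fracture was compared with intact femurs to find which genes follow healing through cartilage. At 4 h, inflammatory signals and stress response genes stood far above the intact level. Cxcl2 and Cxcl1, chemokines that attract neutrophils (chromosome 5, 90903871 to 90905938 and 90891241 to 90893115, GRCm38), rose by 8.08 ± 0.26 and 7.99 ± 0.19. Csf3, the growth factor for neutrophil production, rose by 7.86 ± 0.30. Mean Cxcl2 was 72.9 ± 4.54 scaled RPKM (SD, n = 5) against 0.192 ± 0.115 in intact femurs (SD, n = 10). All 16 inflammatory cytokines and chemokines rose, with a median of 4.73 (camera adjusted p = 2.52e-17, and adjusted p = 0.00187 with an estimated correlation). Among them Il6, a fever and acute phase cytokine, rose by 7.23 ± 0.23. Of 15 immediate early genes, which respond fastest to a stimulus, 14 rose with a median of 3.39 (adjusted p = 3.97e-15, and adjusted p = 0.00864 with an estimated correlation), among them Fosb by 6.05 ± 0.23, Fos by 4.54 ± 0.22 and Junb by 4.03 ± 0.13.

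Also at 4 h after full fracture, 8 of 8 heat shock genes rose (median 1.53), with Hspa1b, an inducible chaperone whose reads are shared with its near copy Hspa1a, at 4.21 ± 0.32. All 18 cell cycle genes (1.28), 12 of 15 neutrophil markers (1.31) and 11 of 11 erythroid markers (1.28) rose, with Ccna2, a cyclin of DNA replication, at 1.59 ± 0.16, Cxcr2, the neutrophil chemokine receptor, at 2.30 ± 0.22 and Slc4a1, the red cell anion exchanger, at 1.65 ± 0.47. For these 4 lists the camera adjusted p ran from 6.07e-09 to 0.0292, and adjusted p from 0.461 to 0.721 with an estimated correlation. Bone cell markers were lower. Of 15 osteoblast markers 12 fell (median -0.78), with Dlx5, a transcription factor of bone formation, at -1.94 ± 0.17, and 10 of 14 osteoclast markers fell (-0.92), with Acp5, the acid phosphatase of resorbing cells (chromosome 9, 22126727 to 22135711), at -1.69 ± 0.29. Of 14 Wnt ligands, targets and antagonists 10 fell and 3 rose (median -0.93), while Wnt1, a ligand that drives bone formation, rose by 2.64 ± 0.25. The adjusted p of these 3 lists ran from 0.00403 to 0.0414, and from 0.705 to 0.721 with an estimated correlation. The Wnt call was also lost on the RPKM as deposited (adjusted p = 0.112), with no filter on low values (adjusted p = 0.0584) and without fractured library 3 (median -0.89, adjusted p = 0.0626). Sln and Myh7, a calcium pump regulator and the myosin of slow muscle fibres, fell by 4.12 ± 0.54 and 2.86 ± 0.40, and Dkk1, a Wnt antagonist, fell by 2.67 ± 0.33. For the 3 largest rises and these 3 falls the fractured femurs did not overlap the 10 intact ones and adjusted p was 3.06e-07 or smaller.

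In all, 5640 genes rose and 5678 fell at 4 h after full fracture, of 19944 tested. Of these, 1567 rose and 1692 fell at least 2-fold. On the RPKM as deposited 4283 rose and 6992 fell, and with upper-quartile scaling 4118 rose and 7683 fell. Those scalings moved the median of all genes from -0.04 to -0.15 and -0.20. Chondrocyte markers stood apart in library 1, whose score was 2.66 against -0.311 to -0.0122 in the other 4 libraries.

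At 1 d after full fracture, cytokine and macrophage genes rose and muscle, fat and respiratory genes fell. Arg1, an enzyme of arginine breakdown made by repair macrophages, rose by 8.19 ± 0.28, from 0.865 ± 0.419 scaled RPKM (SD, n = 10) to 266 ± 67.9 (SD, n = 5). Il11, a cytokine of the interleukin 6 family, rose by 7.51 ± 0.21 and Cxcl2 by 6.65 ± 0.26. Of 16 inflammatory cytokines and chemokines 15 rose, or 16 adjusted over the list alone, with a median of 4.65 (camera adjusted p = 1.55e-19, and adjusted p = 0.000829 with an estimated correlation). Of 15 macrophage markers 12 rose and 1 fell (13 and 1 adjusted over the list alone) with a median of 1.28, among them Cd14, the endotoxin co-receptor, at 3.98 ± 0.19 and Msr1, a scavenger receptor, at 3.68 ± 0.20. Immediate early genes rose in 13 of 15 cases and fell in 1 (median 1.20), cell cycle genes rose in 16 of 18 (0.70) and heat shock genes in 8 of 8 (1.12). Of 13 matrix proteases and inhibitors 7 rose and 3 fell (median 1.61), with Mmp3, a matrix protease, at 3.86 ± 0.33. For these 5 lists adjusted p ran from 7.07e-07 to 0.0083, and from 0.277 to 0.612 with an estimated correlation.

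Lower at 1 d after full fracture were 9 of 9 adipocyte markers (median -1.96), with Adipoq, the fat hormone adiponectin, at -2.28 ± 0.29, and 15 of 15 oxidative phosphorylation genes (-0.73). Muscle markers fell in 12 of 13 cases, or 13 adjusted over the list alone (median -1.15), and osteoclast markers fell in 9 of 14 and rose in 1 (-0.93), with Calcr, the calcitonin receptor, at -2.30 ± 0.33. The adjusted p of these 4 lists ran from 0.000109 to 0.0083, and from 0.347 to 0.612 with an estimated correlation. The largest falls by the fixed rule were Cyp2e1, a cytochrome P450 of liver and fat, at -5.13 ± 0.58, Mylk4, a muscle kinase, at -3.79 ± 0.39 and Myh7 at -3.55 ± 0.40 (adjusted p of 8.24e-09 or smaller). Of 19944 genes, 5325 rose and 4945 fell, 957 and 1581 of them at least 2-fold. The split was 5834 up and 4177 down on the RPKM as deposited, and with upper-quartile scaling 4118 rose and 6281 fell, as the median of all genes moved from -0.03 to 0.04 and -0.14. The chondrocyte score was 1.53 in library 4 against -0.662 to -0.441 in the other 4 libraries.

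At 3 d after full fracture, macrophage, matrix and muscle repair genes were high while blood cell, fat and mature muscle markers fell. Arg1 was still up by 6.00 ± 0.28 and Il11 by 5.28 ± 0.21, and Has2, which makes hyaluronan for early callus matrix, by 5.08 ± 0.21. Of 15 macrophage markers 14 rose and 1 fell (median 1.73), and of 16 inflammatory cytokines and chemokines 13 rose and 1 fell (2.33). Fibrous matrix genes rose in 15 of 16 cases (1.60), with Cthrc1, a collagen-associated protein of healing tissue, at 2.86 ± 0.27. Of 13 matrix proteases and inhibitors 11 rose and 1 fell (1.49; 12 and 1 adjusted over the list alone), with Timp1, a metalloprotease inhibitor, at 3.29 ± 0.20. All 7 muscle regeneration markers rose (2.82), among them Tmem8c, the myoblast fusion protein myomaker, at 5.74 ± 0.40 and Myog, the myogenin transcription factor, at 3.80 ± 0.45. Cell cycle genes rose in 16 of 18 cases (0.79). For these 6 lists adjusted p ran from 5.04e-07 to 0.00101, and from 0.21 to 0.522 with an estimated correlation. Of 15 chondrocyte markers 7 rose and 1 fell (1.15, adjusted p = 0.133, and adjusted p = 0.742 with an estimated correlation), with Sox9, the master regulator of cartilage (chromosome 11, 112782224 to 112787760), at 3.26 ± 0.27 and Acan, the cartilage proteoglycan aggrecan (chromosome 7, 79053483 to 79115099), at 3.47 ± 0.47.

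Marrow and blood markers fell at 3 d after full fracture in 11 of 11 erythroid (median -4.03), 7 of 8 platelet (-2.39), 9 of 11 B cell (-2.33), 8 of 10 T cell (-1.25; 9 adjusted over the list alone) and 11 of 15 neutrophil markers (-1.02). Slc4a1 fell by 4.69 ± 0.47. All 9 adipocyte (-3.02), 13 of 13 muscle (-2.32) and 15 of 15 oxidative phosphorylation members (-1.01) fell as well. The steepest falls were in slow muscle genes, Myl3 at -5.55 ± 0.43, Myl2 at -5.49 ± 0.41 and Myh7 at -5.19 ± 0.40 (adjusted p of 2.02e-12 or smaller). Of 8 osteocyte markers 6 fell and 1 rose (-1.90; 7 and 1 adjusted over the list alone). Sost, the osteocyte Wnt antagonist sclerostin (chromosome 11, 101962458 to 101967015), fell by 3.39 ± 0.29. For these 9 lists adjusted p ran from 9.5e-08 to 0.0184, and from 0.266 to 0.683 with an estimated correlation. The neutrophil call was lost without fractured library 1 (median -0.79, adjusted p = 0.0812) and without library 4 (-0.61, adjusted p = 0.0849). Of 19944 genes 5751 rose and 5592 fell, 1342 and 2285 of them at least 2-fold, against 6196 and 4917 on the RPKM as deposited and 5210 and 6244 with upper-quartile scaling.

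At 7 d after full fracture the section held a strong cartilage programme. Col9a1, a collagen of cartilage fibrils, rose by 8.76 ± 0.59, from 1.13 ± 0.205 scaled RPKM (SD, n = 10) to 542 ± 144 (SD, n = 5). Matn3, a cartilage matrix adaptor, rose by 8.69 ± 0.45 and Clec3a, a cartilage lectin, by 8.64 ± 0.76. Of 15 chondrocyte markers 14 rose with a median of 6.80, among them Acan at 6.80 ± 0.47, Sox9 at 4.89 ± 0.27 and Col2a1, the main cartilage collagen (chromosome 15, 97975602 to 98004695), at 5.66 ± 0.57. All 6 hypertrophic chondrocyte markers rose (3.99), with Col10a1, the collagen of mature cartilage cells (chromosome 10, 34389981 to 34397085), at 8.40 ± 0.67. All 16 fibrous matrix genes rose (2.49), with Fn1, fibronectin, at 4.04 ± 0.17, and so did 11 of 13 matrix proteases and inhibitors with 1 fall (1.85). Tendon markers rose in 5 of 6 cases (1.62), with Tnmd, a tendon membrane protein, at 3.71 ± 0.33. For these 5 lists adjusted p ran from 1.9e-09 to 0.0172, and from 0.309 to 0.434 with an estimated correlation. Osteoblast markers split, with 9 up and 3 down of 15 (median 0.71, adjusted p = 0.225). Ibsp, bone sialoprotein (chromosome 5, 104299171 to 104311469), rose by 2.64 ± 0.23, while Bglap, osteocalcin (chromosome 3, 88383501 to 88384464), fell by 3.18 ± 0.42.

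Osteocyte markers fell in 7 of 8 cases and rose in 1 at 7 d after full fracture (median -1.66), with Sost at -4.08 ± 0.29 and Mepe, a mineral regulator of osteocytes, at -3.07 ± 0.25. Erythroid markers fell in 11 of 11 (-4.71), platelet in 8 of 8 (-4.36), neutrophil in 14 of 15 (-1.39; 15 adjusted over the list alone) and T cell in 8 of 10 (-1.28), and B cell markers fell in 10 of 11 and rose in 1 (-3.14). Muscle in 13 of 13 (-2.57), adipocyte in 9 of 9 (-3.43) and oxidative phosphorylation in 14 of 15 (-0.91) also fell. For these 9 lists adjusted p ran from 3.86e-07 to 0.0162, and from 0.309 to 0.526 with an estimated correlation. By the fixed rule the largest falls were Slc4a1 at -5.39 ± 0.47, Ppbp, a platelet chemokine, at -5.34 ± 0.37 and Cldn13, a claudin of red cell precursors, at -5.29 ± 0.53 (adjusted p of 1.96e-10 or smaller). Library 1 had an erythroid score of -2.34 against -5.45 to -4.75 in the other 4, and without it Slc4a1 was at -6.10 ± 0.39 and Cldn13 at -6.16 ± 0.40. Of 19944 genes 6491 rose and 6704 fell, 2150 and 3154 of them at least 2-fold. On the RPKM as deposited 4749 rose and 8573 fell. The median of all genes moved from -0.08 to -0.28, and to -0.22 with upper-quartile scaling.

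At 14 d after full fracture, resorbing and bone-forming genes had joined mature cartilage genes. Col10a1 was up by 6.59 ± 0.67, at 1003 ± 709 scaled RPKM (SD, n = 5) against 7.09 ± 0.732 (SD, n = 10), Clec3a by 5.73 ± 0.76 and Panx3, a channel of bone and cartilage cells, by 5.71 ± 0.34. Without library 1 the rise of Col10a1 was 7.24 ± 0.66. All 14 osteoclast markers rose with a median of 2.88, among them Dcstamp and Ocstamp, which drive osteoclast fusion, at 3.81 ± 0.30 and 3.94 ± 0.29, Ctsk, the collagen-degrading cathepsin K, at 3.42 ± 0.26 and Acp5 at 3.07 ± 0.29. Of 15 osteoblast markers 13 rose (1.54), with Ibsp at 3.04 ± 0.23 and Sp7, the osterix transcription factor, at 1.60 ± 0.17. Chondrocyte markers rose in 13 of 15 cases and fell in 1 (3.64), hypertrophic ones in 5 of 6 (3.59), fibrous matrix genes in 11 of 16 (1.14) and matrix proteases and inhibitors in 10 of 13 (1.48), with Mmp13, the collagenase of cartilage removal, at 3.27 ± 0.30. For these 6 lists adjusted p ran from 3.98e-09 to 0.000215, and from 0.222 to 0.441 with an estimated correlation.

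Marrow markers were low at 14 d after full fracture. All 15 neutrophil markers fell (median -2.78), with Mpo, the neutrophil granule peroxidase, at -3.09 ± 0.35, and so did 8 of 8 platelet markers (-3.97) and 10 of 11 erythroid markers, with 1 rise (-2.63). Muscle markers fell in 13 of 13 cases (-2.19), adipocyte markers in 9 of 9 (-2.95) and oxidative phosphorylation genes in 14 of 15 (-0.71). For these 6 lists adjusted p ran from 1.36e-07 to 0.000684, and from 0.222 to 0.578 with an estimated correlation. Cyp2e1 fell by 4.54 ± 0.58, and the platelet genes Ly6g6f and Gp9, the latter part of the von Willebrand factor receptor, had values of -4.46 ± 0.38 and -4.37 ± 0.39 (adjusted p of 1.25e-07 or smaller for the 3 largest changes each way). Of 19944 genes 5769 rose and 5381 fell, 1310 and 2275 of them at least 2-fold, against 5286 and 5518 on the RPKM as deposited and 5122 and 6103 with upper-quartile scaling. The scores of single libraries are plotted by time for 9 lists.

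**Figure D2:**
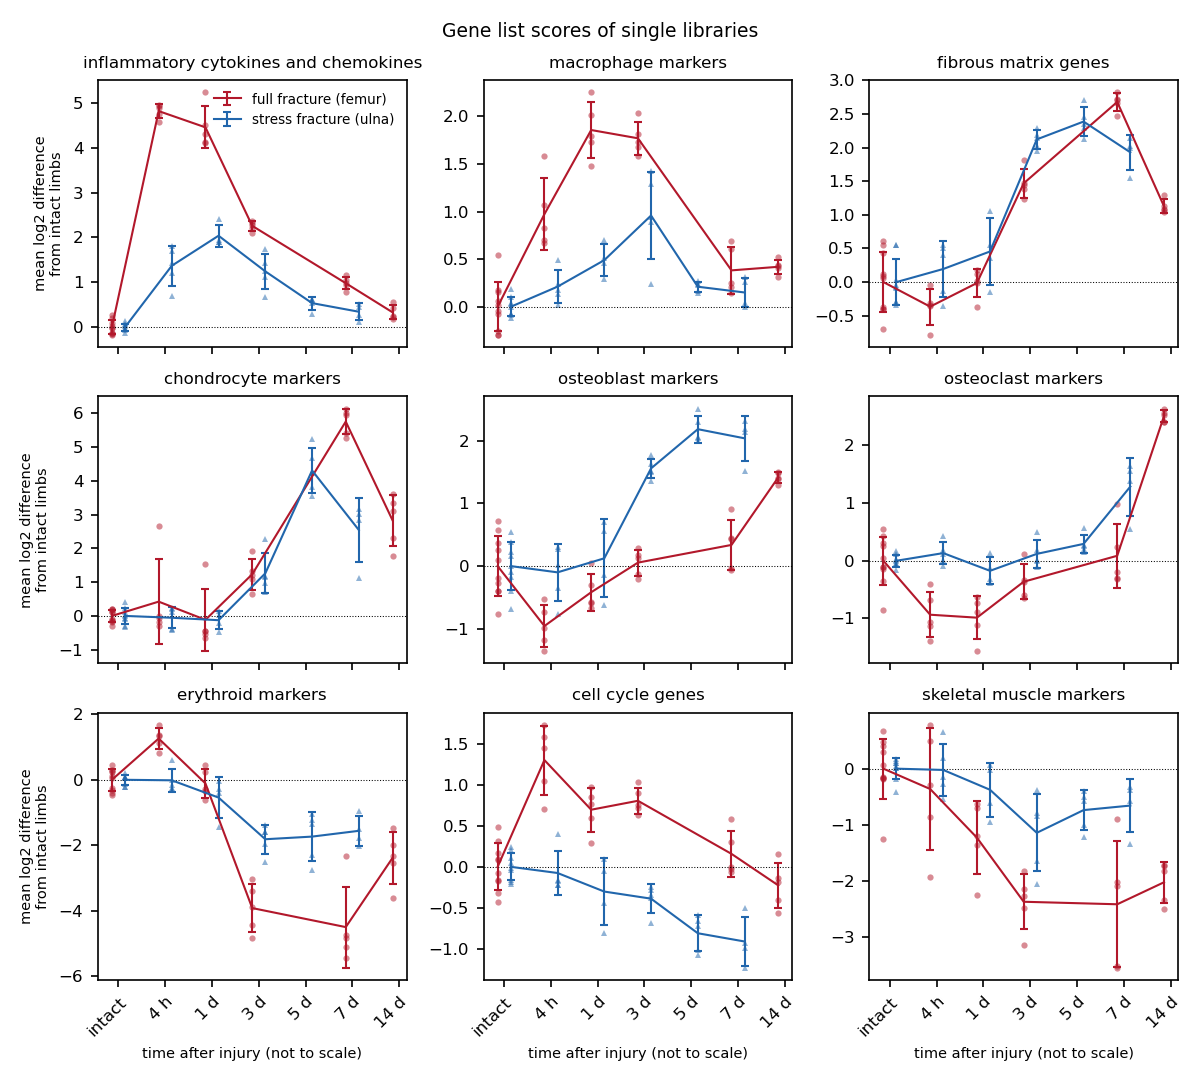
List scores (mean log2 difference of the list's genes from the intact limbs of the same bone, y axis) of single libraries by time after injury (x axis, not to scale) for femurs after full fracture (red) and ulnas after stress fracture (blue), with lines through group means and bars of 1 SD (n = 4 or 5, intact 10 and 9). The median cytokine change was 4.73 at 4 h after full fracture, while chondrocyte scores were highest at 7 d after full and 5 d after stress fracture.

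Stress fracture times were compared with intact ulnas to find which genes follow healing of the intramembranous kind. At 4 h after stress fracture, immediate early genes and inflammatory cytokines rose. Mt2, a metal-binding stress protein, rose by 5.00 ± 0.50, from 34.6 ± 60.1 scaled RPKM (SD, n = 9) to 648 ± 318 (SD, n = 5), Rrad, a small GTPase, by 3.40 ± 0.34 and Socs3, a brake on cytokine signalling, by 2.56 ± 0.18. Mt2 was uneven in intact ulnas, at 36.1 and 193 in libraries 1 and 2 and 7.05 to 16.4 in the others, against 212 to 1016 in injured ulnas. Of 15 immediate early genes 14 rose with a median of 0.92 (camera adjusted p = 4.22e-21, and adjusted p = 0.00142 with an estimated correlation), among them Atf3 at 2.43 ± 0.37 and Fosb at 2.21 ± 0.45. Of 15 inflammatory cytokines and chemokines 8 rose, or 11 adjusted over the list alone (median 0.75, adjusted p = 4.84e-12, and adjusted p = 0.0109 with an estimated correlation), with Cxcl1 at 3.88 ± 0.27, Ccl2, a monocyte chemokine, at 2.87 ± 0.31 and Il6 at 2.34 ± 0.36. Ptgs2, the inducible prostaglandin synthase (chromosome 1, 150100031 to 150108227), rose by 2.78 ± 0.28 and Wnt1 by 2.71 ± 0.30. Of 12 matrix proteases and inhibitors 6 rose and 1 fell (7 and 1 adjusted over the list alone; median 0.66, adjusted p = 5.78e-05, and adjusted p = 0.276 with an estimated correlation). Sost fell by 1.27 ± 0.16, Dkk1 and Dbp, a clock-controlled transcription factor, had values of -1.40 ± 0.18 and -1.31 ± 0.43 (adjusted p of 0.0448 or smaller). The Dbp call was lost without any 1 of 11 of the 14 libraries, injured libraries 1 to 4 and intact libraries 4 to 10 (adjusted p from 0.0514 to 0.143). Of 20506 genes 1129 rose and 1064 fell, 193 and 91 of them at least 2-fold. On the RPKM as deposited 744 rose and 1524 fell, and with upper-quartile scaling 932 rose and 1335 fell.

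At 1 d after stress fracture, inflammatory cytokines and matrix proteases and inhibitors rose. Ccl7 and Ccl2 rose by 4.94 ± 0.48 and 4.46 ± 0.34, and Il11 by 4.46 ± 0.33. Ccl2 stood at 12.6 ± 4.32 scaled RPKM (SD, n = 4) against 0.459 ± 0.138 (SD, n = 9). Of 15 inflammatory cytokines and chemokines 10 rose, or 11 adjusted over the list alone (median 1.66, adjusted p = 1.89e-15, and adjusted p = 0.0049 with an estimated correlation). Of 12 matrix proteases and inhibitors 7 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.87, adjusted p = 1.6e-08, and adjusted p = 0.147 with an estimated correlation), with Mmp3 at 3.08 ± 0.37 and Timp1 at 3.00 ± 0.24. Immediate early genes rose in 7 of 15 cases, or 8 adjusted over the list alone (0.38, adjusted p = 0.000384, and adjusted p = 0.336 with an estimated correlation), with Junb at 1.46 ± 0.16. Inmt, a methyltransferase, fell by 3.05 ± 0.48, Pck1, the enzyme that starts glucose synthesis, by 1.79 ± 0.50 and Klhl33 by 1.78 ± 0.35 (adjusted p of 0.0155 or smaller). Without library 1 Pck1 was at -1.25 ± 0.51 (adjusted p = 0.116), and without library 5 Inmt was at -3.65 ± 0.47. Of 20506 genes 1810 rose and 816 fell, 231 and 88 of them at least 2-fold. Without library 2 of this group 1686 genes changed in place of 2626.

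At 3 d after stress fracture, fibrous matrix and bone-forming genes rose together. C1qtnf3, a secreted protein of cartilage and bone cells, rose by 4.81 ± 0.34, Panx3 by 4.46 ± 0.28 and Car12, a carbonic anhydrase, by 4.05 ± 0.31. Fibrous matrix genes rose in 15 of 16 cases with a median of 2.21, among them Cthrc1 at 4.04 ± 0.32 and Lox, which crosslinks collagen, at 3.17 ± 0.29. Of 15 osteoblast markers 12 rose, or 14 adjusted over the list alone (1.54), with Ibsp at 2.58 ± 0.26, Ifitm5, an osteoblast membrane protein, at 2.79 ± 0.25 and Col1a1, the main bone collagen, at 2.37 ± 0.38. All 12 matrix proteases and inhibitors rose (1.61), and so did 12 of 15 macrophage markers (0.93; 13 adjusted over the list alone) and 8 of 15 inflammatory cytokines and chemokines, with 1 fall (0.88; 9 and 1 adjusted over the list alone). Of 16 Wnt ligands, targets and antagonists 10 rose and 2 fell (0.56), with Sfrp2, a secreted Wnt binder, at 3.16 ± 0.28. Chondrocyte markers rose in 7 of 15 cases and fell in 1 (0.94), with Acan at 3.81 ± 0.35. Tendon markers rose in 5 of 6 (0.97) and muscle regeneration markers in 4 of 7 (1.53), with Tmem8c at 4.77 ± 0.62, or 5.46 ± 0.58 without library 4 and 4.10 ± 0.59 without library 5. For these 9 lists adjusted p ran from 6.51e-15 to 0.0122, and from 0.165 to 0.395 with an estimated correlation. Library 4 had a chondrocyte score of 2.27 against 0.718 to 1.17 in the other 4 and Col2a1 at 62.8 scaled RPKM against 5.88 to 8.90, and without it the chondrocyte median was 0.46 (adjusted p = 0.0275).

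Erythroid markers fell in 11 of 11 cases at 3 d after stress fracture (median -1.87), with Slc4a1 at -1.83 ± 0.28. Platelet markers fell in 7 of 8 (-0.75; 8 adjusted over the list alone), B cell in 8 of 12 (-1.35; 9 adjusted over the list alone) and T cell in 6 of 11 (-0.71; 8 adjusted over the list alone). Muscle markers fell in 13 of 13 (-1.12), oxidative phosphorylation genes in 15 of 15 (-0.51), cell cycle genes in 12 of 18 (-0.42; 13 adjusted over the list alone) and Schwann cell markers in 6 of 7 (-0.48; 7 adjusted over the list alone). For these 8 lists adjusted p ran from 4.4e-09 to 0.0102, and from 0.241 to 0.462 with an estimated correlation. The largest falls by the fixed rule were Odf3l2 at -3.48 ± 0.78, Inmt at -2.35 ± 0.44 and Hist3h2ba, a histone, at -2.28 ± 0.37 (adjusted p of 0.000725 or smaller). Odf3l2 was uneven in intact ulnas, at 39.5 and 24.1 scaled RPKM in libraries 1 and 2 and 1.15 to 11.3 in the others. In the injured ulnas it stood at 0.0588 to 1.15, up to the lowest intact value. Of 20506 genes 4150 rose and 3606 fell, 849 and 568 of them at least 2-fold, against 3442 and 4322 on the RPKM as deposited and 3619 and 4381 with upper-quartile scaling.

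At 5 d after stress fracture, cartilage genes rose steeply beside bone-forming genes. Matn3 rose by 7.14 ± 0.43, from 0.0811 ± 0.068 scaled RPKM (SD, n = 9) to 30.0 ± 23.0 (SD, n = 5), Panx3 by 6.83 ± 0.28 and C1qtnf3 by 6.35 ± 0.34. Of 15 chondrocyte markers 13 rose and 1 fell with a median of 5.29, among them Col2a1 at 6.25 ± 0.57 and Acan at 5.29 ± 0.35, whereas Sox6, a cartilage transcription factor also made by red cell precursors, fell by 0.67 ± 0.16. All 6 hypertrophic chondrocyte markers rose (2.74), with Col10a1 at 4.88 ± 0.51. All 15 osteoblast markers rose (2.19), with Ibsp at 4.03 ± 0.26, Smpd3, a sphingomyelinase needed for mineralisation, at 3.98 ± 0.30 and Col1a1 at 3.11 ± 0.38. All 16 fibrous matrix genes (2.46), 11 of 12 matrix proteases and inhibitors (2.08; 12 adjusted over the list alone) and 6 of 6 tendon markers (1.13) rose, and Wnt members rose in 12 of 16 cases and fell in 2 (1.03), with Sfrp1, a Wnt binder, at 2.24 ± 0.22. For these 7 lists adjusted p ran from 1.06e-14 to 0.00156, and from 0.0771 to 0.165 with an estimated correlation.

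All 18 cell cycle genes fell at 5 d after stress fracture (median -0.79), with Mki67, a marker of dividing cells, at -1.23 ± 0.19. All 15 neutrophil (-1.11), 11 of 11 erythroid (-1.76), 8 of 8 platelet (-1.002), 9 of 11 T cell (-1.11; 10 adjusted over the list alone) and 5 of 12 B cell markers (-0.90; 6 adjusted over the list alone) fell. Muscle markers fell in 12 of 13 cases (-0.70) and Schwann cell markers in 4 of 7 (-0.45; 6 adjusted over the list alone). For these 8 lists adjusted p ran from 5.37e-09 to 0.0239, and from 0.189 to 0.452 with an estimated correlation. Without library 2 the B cell median was -0.57 (adjusted p = 0.0219), and without library 3 the Schwann cell call was lost (-0.36, adjusted p = 0.0557). By the fixed rule the largest falls were Hist3h2ba at -2.14 ± 0.37, Hbq1b, a globin, at -1.97 ± 0.37 and Ermap, a red cell membrane protein, at -1.92 ± 0.29 (adjusted p of 6.96e-05 or smaller). Of 20506 genes 4579 rose and 4294 fell, 1132 and 721 of them at least 2-fold. On the RPKM as deposited 3158 rose and 7130 fell, as the median of all genes moved from -0.03 to -0.18, and with upper-quartile scaling 4051 rose and 5216 fell.

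At 7 d after stress fracture, osteoclast and osteocyte genes had risen and cartilage genes were also above intact ulnas. Panx3 was up by 5.32 ± 0.30, Car12 by 5.15 ± 0.34 and Col10a1 by 4.71 ± 0.54. Of 15 osteoblast markers 14 rose with a median of 2.06, with Smpd3 at 3.22 ± 0.33 and Bglap at 2.17 ± 0.56. Osteoclast markers rose in 12 of 14 cases (1.43; 12 with 1 fall adjusted over the list alone), with Ocstamp at 2.94 ± 0.26, Ctsk at 2.12 ± 0.21 and Acp5 at 1.42 ± 0.22. Of 8 osteocyte markers 5 rose (1.09; 5 with 1 fall adjusted over the list alone), with Phex and Dmp1, regulators of mineral and phosphate, at 1.75 ± 0.17 and 1.56 ± 0.23. Chondrocyte markers rose in 13 of 15 cases and fell in 1 (2.94), hypertrophic ones rose in 5 of 6 (2.06; 6 adjusted over the list alone), fibrous matrix genes in 15 of 16 (1.82), matrix proteases and inhibitors in 10 of 12 (1.61), tendon markers in 6 of 6 (0.97) and Wnt members in 9 of 16 with 1 fall (0.81; 10 and 1 adjusted over the list alone). For these 9 lists adjusted p ran from 8.57e-15 to 0.00327, and from 0.0796 to 0.22 with an estimated correlation. Library 4 had a chondrocyte score of 1.14 against 2.83 to 3.17 in the other 3, and without it Col10a1 was up by 5.67 ± 0.44.

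All 18 cell cycle genes fell at 7 d after stress fracture (median -0.90), with Mki67 at -1.05 ± 0.20. Blood markers fell in 11 of 11 erythroid (-1.59), 13 of 15 neutrophil (-0.80; 15 adjusted over the list alone), 8 of 8 platelet (-0.82), 5 of 12 B cell (-1.01; 6 adjusted over the list alone) and 6 of 11 T cell cases (-0.77; 8 adjusted over the list alone). Muscle markers fell in 5 of 13 (-0.71; 7 adjusted over the list alone) and oxidative phosphorylation genes in 11 of 15 (-0.45; 14 adjusted over the list alone). For these 8 lists adjusted p ran from 1.66e-12 to 0.00684, and from 0.161 to 0.387 with an estimated correlation. The largest falls were in globins, near copies whose reads are hard to assign, with Hbb-bs at -1.79 ± 0.33, Hbb-bt at -1.73 ± 0.33 and Hba-a2 at -1.72 ± 0.31 (adjusted p of 0.000161 or smaller). Of 20506 genes 3799 rose and 3286 fell, 861 and 422 of them at least 2-fold. The split was 2937 up and 4744 down on the RPKM as deposited.

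The overlap of both injuries was counted at the 4 matched times over 19030 genes tested in both bones, which share no control libraries. At 4 h, 887 genes rose and 881 fell after both injuries, against 318 and 286.5 by chance. At 1 d the shared numbers were 1399 and 529 against 483 and 195, at 3 d 3177 and 2683 against 1200 and 966.5, and at 7 d 2664 and 2037 against 1227 and 1079 (odds ratios from 4.59 to 22.9, Fisher's exact p of 7.91e-147 or smaller). Fisher's test takes genes as independent, which they are not, so its p does not measure the spread between animals. Opposite calls were fewer, with 14 genes at 4 h and 424 at 7 d up after full and down after stress fracture, and 23 and 308 the reverse. Log2 changes of the injuries correlated across genes with Pearson r of 0.40 at 4 h, 0.40 at 1 d, 0.66 at 3 d and 0.54 at 7 d, and genes are not independent replicates. Wnt1 rose after both injuries at 4 h, and its difference was -0.05 ± 0.40 (adjusted p = 0.94).

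The response to full fracture minus that to stress fracture was tested at each matched time to find where the injuries part. At 4 h the neutrophil signals Csf3 (6.49 ± 0.46), Cxcl2 (6.41 ± 0.40) and Cxcl3 (5.63 ± 0.30) and Il6 (4.97 ± 0.40) rose more after full fracture. The muscle genes with the lowest differences were Sln at -4.57 ± 0.65, Myl3 at -3.06 ± 0.59, Tnnc1 at -2.89 ± 0.55 and Tnni1 at -2.88 ± 0.62 (adjusted p of 0.000186 or smaller). Their levels in intact ulnas were low (Sln from 2.20 to 4.46 and Tnni1 from 0.571 to 1.31 scaled RPKM, against 16.2 to 148 and 31.1 to 192 in intact femurs). At 4 h after stress fracture Sln was 2.25 to 8.91 and Tnni1 0.696 to 1.53, not below the intact range. Whether the low start shaped these differences was not tested. Of 16 inflammatory cytokines and chemokines 15 rose more after full fracture, or 16 adjusted over the list alone (median difference 3.71, adjusted p = 3.33e-22, and adjusted p = 8.7e-05 with an estimated correlation). Immediate early genes did in 13 of 15 cases, or 14 adjusted over the list alone (1.88, adjusted p = 2.51e-15, and adjusted p = 0.00297 with an estimated correlation), with Fosb at 3.86 ± 0.51. Heat shock genes had higher differences in 5 of 8 cases (1.32), cell cycle genes in 18 of 18 (1.32) and neutrophil markers in 10 of 15 (1.28; 11 adjusted over the list alone), and osteoclast markers lower ones in 11 of 14 (-1.32; 12 adjusted over the list alone), with Acp5 at -1.70 ± 0.37. For these 4 lists adjusted p ran from 3.28e-14 to 0.000331, and from 0.157 to 0.717 with an estimated correlation. Of 21092 genes the difference was positive for 3757 and negative for 3846, and with upper-quartile scaling for 2842 and 5342, as the median of all genes moved from -0.07 to -0.18. Bone, injury, section length, the gene names in the tables and the removal of marrow changed together, so a difference belongs to no single one of them.

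At 1 d the difference was largest for Arg1 (5.59 ± 0.62), Cxcl3 (5.22 ± 0.31), Cxcl2 (5.05 ± 0.42) and Hcar2, a metabolite receptor of myeloid cells (4.35 ± 0.30). It was most negative for Tnnc1 (-3.63 ± 0.57), Sln (-3.63 ± 0.68), Tnni1 (-3.61 ± 0.65) and Cyp2e1 (-3.21 ± 0.78; adjusted p of 0.00153 or smaller), the last at -3.88 ± 0.79 without library 1 at 1 d after stress fracture. Of these Tnnc1, Sln and Tnni1 had low levels in intact ulnas. Inflammatory cytokines and chemokines had higher differences in 13 of 16 cases, or 16 adjusted over the list alone (2.37, adjusted p = 6.2e-18, and adjusted p = 0.000579 with an estimated correlation). Immediate early genes did in 9 of 15 (0.87), heat shock genes in 5 of 8 (0.74), cell cycle genes in 17 of 18 (1.00; 18 adjusted over the list alone) and macrophage markers in 12 of 15 (1.03), with Cd14 at 2.93 ± 0.30. Of 16 Wnt members 8 had lower and 1 had higher differences (-0.59; 9 and 1 adjusted over the list alone). For these 5 lists adjusted p ran from 5.31e-11 to 0.0408, and from 0.169 to 0.564 with an estimated correlation. The Wnt call was lost without any 1 of 7 libraries, intact femurs 8 and 9, fractured femurs 3 and 4, intact ulnas 6 and 10 and stress fracture library 2 (adjusted p from 0.0504 to 0.164). Positive differences numbered 2915 and negative ones 2819, against 3807 and 2036 on the RPKM as deposited, as the median of all genes moved from -0.06 to 0.04, and 2380 and 3503 with upper-quartile scaling.

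At 3 d Arg1 (3.27 ± 0.60), Gzme, a granzyme (2.97 ± 0.48), Hmox1, which breaks down heme (2.96 ± 0.31), and Actg2, a smooth muscle actin (2.82 ± 0.45), had the highest differences. Retnla, a product of repair macrophages and fat (-4.65 ± 0.96), Tnnc1 (-4.56 ± 0.55), Bglap (-4.54 ± 0.68) and Myh7 (-4.43 ± 0.55) had the lowest differences (adjusted p of 0.000191 or smaller), of which Tnnc1 and Myh7 had low levels in intact ulnas. Library 4 at 3 d after stress fracture stood apart in Retnla (226 scaled RPKM against 0.613 to 2.02 in the other 4) and in Arg1 (68.2 against 0.908 to 4.42). Without it the difference in Retnla was -3.14 ± 0.69 and that in Arg1 4.29 ± 0.39. Osteoblast markers had lower differences in 10 of 15 cases (median -1.47), with Col1a1 at -1.88 ± 0.46, and osteocyte markers in 7 of 8 (-1.73, and 8 adjusted over the list alone), with Sost at -2.78 ± 0.34. Col1a1 levels at 3 d overlapped (4770 to 6358 scaled RPKM in injured femurs and 4246 to 5916 in injured ulnas), from lower levels in intact ulnas than in intact femurs. Sost was lower in the injured femurs themselves (16.5 to 38.7 against 77.3 to 123). Cell cycle genes had higher differences in 17 of 18 (1.24; 18 adjusted over the list alone), macrophage markers in 9 of 15 with 1 lower (0.80; 12 and 1 adjusted over the list alone) and inflammatory cytokines and chemokines in 8 of 16 with 1 lower (1.01). Erythroid markers had lower differences in 11 of 11 (-2.16), platelet in 7 of 8 (-1.61), muscle in 7 of 13 (-1.24; 10 adjusted over the list alone), adipocyte in 8 of 9 (-2.40) and mast cell markers in 4 of 6 (-1.38; 5 adjusted over the list alone). Of 16 Wnt members 7 had lower and 1 higher differences (-0.60; 8 and 1 adjusted over the list alone). For these 11 lists adjusted p ran from 7.74e-17 to 0.0341, and from 0.194 to 0.647 with an estimated correlation. The Wnt call was lost without intact femur 8 or 9 or stress fracture library 1 (adjusted p from 0.0534 to 0.0668). Positive differences numbered 2673 and negative ones 2867, against 3637 and 2127 on the RPKM as deposited, as the median of all genes moved from -0.06 to 0.05.

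At 7 d the changes of cartilage genes were higher and those of mature bone genes lower after full than after stress fracture. Gzme (6.51 ± 0.50), Ucma, a secreted cartilage protein (6.47 ± 0.79), Moxd1 (6.05 ± 0.41) and Matn1, a cartilage matrix protein (5.92 ± 0.69), had the highest differences. Bglap (-5.35 ± 0.70) and its near copy Bglap2 (-5.06 ± 0.61), Myoc, myocilin (-4.93 ± 0.54), and Ppbp (-4.48 ± 0.45) had the lowest (adjusted p of 7.24e-09 or smaller for these 8). Chondrocyte markers had higher differences in 11 of 15 cases (median 3.93; 11 with 1 lower adjusted over the list alone), with Sox9 at 3.29 ± 0.39, although the difference in Col2a1 was 1.25 ± 0.86 (adjusted p = 0.23). Without library 4 at 7 d after stress fracture the chondrocyte median was 3.18, Ucma at 5.82 ± 0.81 and Col2a1 at 0.42 ± 0.86. Osteoblast markers had lower differences in 11 of 15 (-1.17), with Col1a1 at -2.29 ± 0.47. So did 7 of 8 osteocyte markers (-2.90), with Sost at -3.72 ± 0.36 and Dmp1 at -3.00 ± 0.33, and 13 of 14 osteoclast markers (-1.38), with Acp5 at -1.50 ± 0.38. Levels at 7 d overlapped between injured femurs and ulnas for Col1a1 (4910 to 9343 and 5614 to 10270 scaled RPKM) and Acp5 (160 to 502 and 81.7 to 227). Both started lower in intact ulnas (380 to 2264 and 43.6 to 78.1) than in intact femurs (2243 to 7300 and 110 to 407). Bglap (30.6 to 123 against 468 to 622) and Sost (9.72 to 40.4 against 106 to 132) were lower in the injured femurs themselves. Cell cycle genes had higher differences in 17 of 18 (1.05). Erythroid (10 of 11, -3.18; 11 adjusted over the list alone), platelet (8 of 8, -3.60), B cell (9 of 12, -1.84; 10 adjusted over the list alone), muscle (13 of 13, -1.81), adipocyte (7 of 9, -2.69) and mast cell markers (6 of 6, -1.70) had lower differences. For these 11 lists adjusted p ran from 2.76e-07 to 0.0159, and from 0.235 to 0.736 with an estimated correlation. Without library 1 at 7 d after full fracture the erythroid median was -3.78. Positive differences numbered 4964 and negative ones 4947, against 3744 and 5833 on the RPKM as deposited and 3927 and 6160 with upper-quartile scaling, as the median of all genes moved from -0.10 to -0.21 and -0.22.

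**Figure D3:**
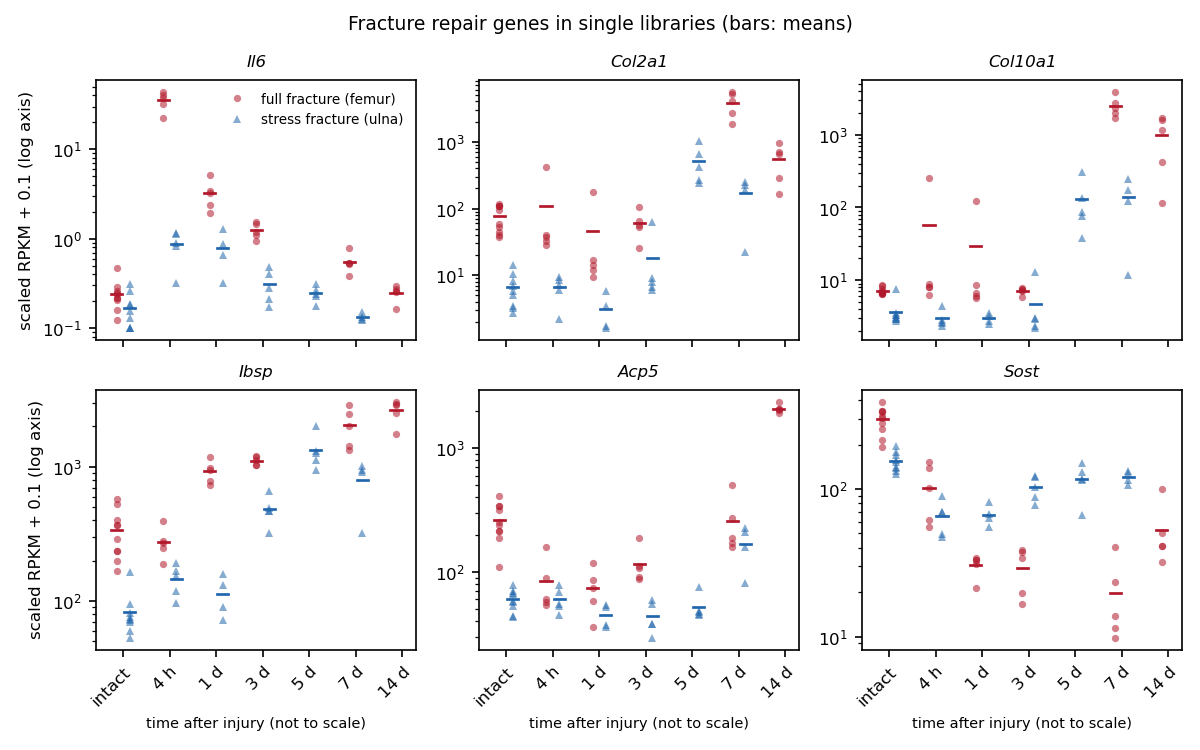
Scaled RPKM + 0.1 (y axis, log scale) of 6 fracture repair genes in single libraries by time after injury (x axis, not to scale), with bars at group means, for femurs after full fracture (red, n = 5 per time, 10 intact) and ulnas after stress fracture (blue, n = 4 or 5, 9 intact). Il6 was highest at 4 h after full fracture (7.23 above intact femurs, log2), while Sost fell by 4.08 at 7 d after full fracture and had a value of -0.36 (adjusted p = 0.11) at 7 d after stress fracture.

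Intact ulnas were compared with intact femurs to describe how the starting tissues differed. Bone, matrix and resorption genes were lower in the ulna sections, and nerve sheath, B cell and erythroid genes were higher. Il4i1, an amino acid oxidase of immune cells (5.39 ± 0.12), Mss51 (3.25 ± 0.30), Chrne, a subunit of the muscle acetylcholine receptor (3.03 ± 0.24), and Inmt (2.95 ± 0.36) were higher in the ulna. Il4i1 stayed at 7.24 to 11.4 scaled RPKM in all ulna and 0.0129 to 0.202 in all femur libraries, injured or intact. Whether this came from the tissue or from how reads were counted in each bone was not tested. The slow muscle genes Myh7 (-7.76 ± 0.32), Myl3 (-6.95 ± 0.34) and Tnnc1 (-6.91 ± 0.32) and Hoxc10, a hind limb patterning gene (-6.62 ± 0.11), were lower in the ulna (adjusted p of 1.18e-09 or smaller for these 8). All 16 fibrous matrix genes were lower (median -1.64), as were 11 of 13 matrix proteases and inhibitors (-0.83; 12 adjusted over the list alone), with adjusted p of 4.02e-16 and 7.18e-08, and 0.0469 for each with an estimated correlation. Osteoblast (15 of 15, -1.95), osteocyte (7 of 8, -1.29) and osteoclast markers (13 of 14, -1.36) were lower, with Col1a1 at -2.26 ± 0.27 and Acp5 at -2.27 ± 0.22, with adjusted p of 8.05e-07 or smaller, and from 0.0559 to 0.12 with an estimated correlation. Schwann cell markers were higher in 7 of 7 cases (1.31, adjusted p = 3.66e-10, and adjusted p = 0.0127 with an estimated correlation). Cell cycle genes (18 of 18, 0.77), B cell markers (10 of 12, 1.20; 12 adjusted over the list alone) and erythroid markers (8 of 11, 0.94; 10 adjusted over the list alone) were higher, with adjusted p from 9.76e-12 to 0.00196, and from 0.216 to 0.469 with an estimated correlation. The other marrow lists, neutrophil (median 0.33, adjusted p = 0.181) and platelet markers (0.22, adjusted p = 0.39), were not called. Of 21092 genes 3794 were higher and 4579 lower in the ulna. Without scaling, on the RPKM as deposited, 8034 were higher and 2139 lower, as the median of all genes moved from -0.01 to 0.20, and with upper-quartile scaling 4599 were higher and 3915 lower.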

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

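Tests of the difference between injuries were planned, while the tests of explanations and the counts of other splits were chosen after the results were seen. By the tested difference, full and stress fracture responses parted in 7603 genes at 4 h, 5734 at 1 d, 5540 at 3 d and 9911 at 7 d. Median log2 differences at 4 h were 3.71 for inflammatory cytokines and chemokines, 1.88 for immediate early genes, 1.32 for heat shock genes, 1.32 for cell cycle genes, 1.28 for neutrophil, -1.32 for osteoclast and -0.85 for mesenchymal progenitor markers. At 1 d they were 2.37 for cytokines, 0.87 for immediate early genes, 0.74 for heat shock genes, 1.00 for cell cycle genes, 1.03 for macrophage markers, -0.59 for Wnt members and -0.69 for mesenchymal progenitor markers. At 3 d they were 1.01 for cytokines, 1.24 for cell cycle genes, 0.80 for macrophage, -2.16 for erythroid, -1.61 for platelet, -1.24 for muscle, -2.40 for adipocyte, -1.47 for osteoblast, -1.73 for osteocyte and -1.38 for mast cell markers and -0.60 for Wnt members. At 7 d they were 1.05 for cell cycle genes, 3.93 for chondrocyte, -3.18 for erythroid, -3.60 for platelet, -1.84 for B cell, -1.81 for muscle, -2.69 for adipocyte, -1.17 for osteoblast, -2.90 for osteocyte, -1.38 for osteoclast and -1.70 for mast cell markers. With an estimated correlation 33 of these 36 list calls were lost (adjusted p from 0.145 to 0.736), all but cytokines at 4 h and 1 d and immediate early genes at 4 h. The calls of the Wnt members were lost at 1 d without any 1 of 7 libraries, intact femurs 8 and 9, fractured femurs 3 and 4, intact ulnas 6 and 10 and stress fracture library 2 (adjusted p from 0.0504 to 0.164), and at 3 d without intact femur 8 or 9 or stress fracture library 1 (from 0.0534 to 0.0668). At 7 d the chondrocyte median was 3.18 without stress fracture library 4 and the erythroid median -3.78 without fractured library 1. Osteoblast, osteocyte and osteoclast markers started lower in intact ulnas than in intact femurs, so their differences do not by themselves mean lower levels after full fracture.

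Single genes with the largest tested differences at 4 h were Csf3 (6.49), Cxcl2 (6.41), Cxcl3 (5.63), Il6 (4.97), Sln (-4.57), Myl3 (-3.06), Tnnc1 (-2.89) and Tnni1 (-2.88), the last 4 from lower levels in intact ulnas than in intact femurs. At 1 d they were Arg1 (5.59), Cxcl3 (5.22), Cxcl2 (5.05), Hcar2 (4.35), Tnnc1 (-3.63), Sln (-3.63), Tnni1 (-3.61) and Cyp2e1 (-3.21). At 3 d they were Arg1 (3.27), Gzme (2.97), Hmox1 (2.96), Actg2 (2.82), Retnla (-4.65), Tnnc1 (-4.56), Bglap (-4.54) and Myh7 (-4.43), and without library 4 at 3 d after stress fracture the values of Retnla and Arg1 were -3.14 and 4.29. At 7 d they were Gzme (6.51), Ucma (6.47), Moxd1 (6.05), Matn1 (5.92), Bglap (-5.35), Bglap2 (-5.06), Myoc (-4.93) and Ppbp (-4.48), and without library 4 at 7 d after stress fracture the difference in Ucma was 5.82. Without library 1 at 1 d after stress fracture the difference in Cyp2e1 at 1 d was -3.88.

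Scores of the 33 lists in the 12 groups and values of genes named by the fixed rule were searched for single libraries far from the rest of their group of 4 to 10. These were found in 25 of 396 list scores and 7 of 130 gene values, where chance gives about 1 in 20, so the totals lie near chance. Some libraries held several items, in part from lists that share genes, as the fracture repair panel does with the chondrocyte lists. Many other libraries held 1 item. Library 4 at 7 d after stress fracture had low scores for chondrocyte (1.14 against 2.83 to 3.17), hypertrophic chondrocyte (1.28 against 3.10 to 3.30), matrix protease (0.981 against 1.58 to 1.68) and fracture repair panel genes (1.00 against 1.87 to 1.97). Library 1 at 4 h after full fracture was high in chondrocyte (2.66 against -0.311 to -0.0122), hypertrophic chondrocyte (1.73 against -0.262 to -0.0602) and fracture repair panel genes (1.62 against 0.803 to 0.984). Library 4 at 1 d after full fracture was high in chondrocyte (1.53 against -0.662 to -0.441), hypertrophic chondrocyte (1.52 against 0.651 to 0.880) and B cell markers (0.801 against -0.978 to -0.467) and low in osteocyte markers (-1.09 against -0.670 to -0.577). Intact femur 2 was high in platelet (0.889 against -0.377 to 0.211) and low in muscle (-1.25 against -0.177 to 0.674) and oxidative phosphorylation genes (-0.639 against -0.155 to 0.365). Library 4 at 3 d after stress fracture was low in mast cell markers (-0.154 against 0.661 to 0.754) and high in Retnla (7.82 against -0.487 to 1.08, log2 scaled RPKM). Library 1 at 7 d after full fracture was high in erythroid markers (-2.34 against -5.45 to -4.75) and in Slc4a1 (4.51 against 0.352 to 1.403, log2 scaled RPKM). Library 2 at 4 h after full fracture was high in interferon response genes (1.43 against 0.388 to 0.667). Library 4 at 1 d after stress fracture was high in cytokines (2.41 against 1.89 to 1.95). Library 4 at 3 d after full fracture was high in oxidative phosphorylation genes (-0.813 against -1.09 to -1.07), and library 3 at 3 d after stress fracture in matrix proteases (2.04 against 1.67 to 1.75). Gp9 was high in library 2 at 14 d after full fracture (1.64 against 0.0379 to 0.325), and library 5 at 4 h after stress fracture was low in Socs3 (4.30 against 5.38 to 5.74) and Il6 (-1.65 against -0.280 to 0.225) and high in cell cycle genes (0.402 against -0.220 to -0.165). At 5 d after stress fracture library 3 was low in cytokines (0.284 against 0.538 to 0.629) and library 4 high in osteoclast markers (0.570 against 0.156 to 0.271). Intact ulna 2 was high in tendon markers (0.624 against -0.246 to 0.170), intact ulna 1 low in mesenchymal progenitor markers (-0.235 against -0.0507 to 0.124), and library 2 at 1 d after full fracture high in Hcar2 (4.93 against 4.11 to 4.32). Hoxc10 stood at -2.56 in intact ulna 10 and at the floor of -3.32 in the other 8.

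Chondrocyte markers were higher at 5 d and 7 d after stress fracture, an injury the series title ties to intramembranous ossification. Growth plate or joint cartilage taken into sections equally often at all times was argued against as the source in all 9 late libraries, since 0 of the 18 intact, 4 h and 1 d ulna libraries reached their lowest chondrocyte score (0.408 against 1.14). At 3 d, when the list was already higher, 3 of 5 did, and library 4 stood apart (2.27 against 0.718 to 1.17, with Col2a1 at 62.8 scaled RPKM against 5.88 to 8.90). The count restates the difference that prompted it, so cartilage taken in more often at late times was not tested. Clec3a was 10.8 and 7.79 scaled RPKM in intact ulnas 2 and 10, within the 4.27 to 28.2 of the late libraries. Col2a1 there was 14.4 and 2.66, below the late 21.9 to 1007. Scaling was argued against too, since the median on the RPKM as deposited was 5.13 at 5 d and 2.87 at 7 d, against 5.29 and 2.94. In 1 femur at 4 h (score 2.66) and 1 at 1 d (1.53) after full fracture chondrocyte scores also stood above the other libraries of their groups. The source of cartilage genes in these single libraries was not tested, so cartilage cut into a few sections stays open. A small cartilage callus in the stress fracture may be the source and stays open as a hypothesis, since no independent measure of cartilage was used.

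Cell cycle genes were lower at 5 d and 7 d after stress fracture and higher at 3 d after full fracture. Within groups the cell cycle and marrow scores of 32 ulna libraries moved together (r = 0.574, permutation p = 0.00318, BH-adjusted 0.00636, rho = 0.527, p = 0.0136). Without the 2 libraries farthest from the median r was 0.537. In the 9 intact ulnas alone no such relation was detected (r = -0.309, exact p = 0.407, BH-adjusted 0.407, rho = -0.200, exact p = 0.613). Without the 2 farthest r was -0.573, and 2 relations were computed in all. Uneven injury could also link the scores, so these relations cannot decide whether less marrow RNA caused the fall. Hbb-bs, an abundant red cell transcript, stood at 962 ± 239 scaled RPKM at 7 d (SD, n = 4) against 3323 ± 765 in intact ulnas (SD, n = 9). More marrow RNA in the femur sections at 3 d was argued against as the source of the rise, since erythroid, B cell and platelet medians were -4.03, -2.33 and -2.39 while that of cell cycle genes was 0.79, and more dividing callus cells stay open and untested.

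Erythroid, neutrophil and cell cycle lists were higher at 4 h after full fracture. It was predicted that more marrow RNA would raise the 4 marrow lists alike, and they rose unequally. Their mean scores rose by 1.28 (neutrophil), 1.26 (erythroid), 0.60 (B cell) and 0.33 (platelet), a range of 0.947 (n = 5 against 10, exact permutation p = 0.000666 over 3003 splits). Erythroid scores lay above platelet scores in 5 of 5 libraries. This cannot decide on marrow RNA, since an equal rise is not assured. Between intact ulnas, with no marrow removal named, and intact femurs the lists also differed unequally. There B cell (median 1.20) and erythroid markers (0.94) were called and neutrophil and platelet markers were not. The 4 lists lay above 0, as more marrow RNA would give, and a fall in platelet RNA itself stays open. Blood in the fracture gap was not tested. Blood or marrow with fewer platelets may still account for part of the rise, and a biological entry of neutrophils stays open and untested.

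In each of the 15 contrasts the real split was the only 1 of 100 splits of the libraries with as many changed genes. The 100 were taken from 126 to 92378 possible splits, so 1 in 100 is the smallest share they can give. For the differences between injuries only injured libraries were exchanged, so chance in the intact libraries was not tested there. Chance is thus an unlikely source of the counts within these limits, but it is not excluded. At 4 h, 1 d, 3 d, 7 d and 14 d after full fracture the real counts were 11318, 10270, 11343, 13195 and 11150 and the highest of the other splits 4782, 1351, 8570, 6150 and 6102. At 4 h, 1 d, 3 d, 5 d and 7 d after stress fracture the real counts were 2193, 2626, 7756, 8873 and 7085 and the highest others 484, 1050, 4456, 3569 and 345. For the differences at 4 h, 1 d, 3 d and 7 d the highest others were 4556, 3474, 869 and 7995 against the counts given above, and for intact ulna against intact femur 2554 against 8373.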

How the results depend on the processing

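Alternatives fixed in advance were RPKM as deposited, upper-quartile scaling, other pseudocounts, other filters, fits of only the 2 groups compared, the authors' calls and leaving out each injured or, for injury contrasts, intact library, while leaving out the libraries that stood apart in a principal component plot and intact libraries in the other contrasts (with a pseudocount of 0.5 and a filter at 1 for intact ulna against intact femur) was chosen after seeing the data. Fits of only the 2 groups and the authors' calls were set beside the 10 injury contrasts alone. Under the alternatives run for each, counts of changed genes stayed within 1.5 times their value except at 1 d after stress fracture, where 1700 genes changed without the libraries that stood apart, against 2626, and from 1686 (without library 2) to 2536 when each library was left out; 3 libraries were left in the group, and the cause was not tested. Leaving out each library gave from 1547 to 2483 genes at 4 h after stress fracture and from 12504 to 13198 at 7 d after full fracture. Of 438 values of named and panel genes, 423 kept their side of the threshold and their direction on the RPKM as deposited, 11 lost and 3 gained the call, and Pecam1, an endothelial adhesion gene not called in intact ulna against intact femur (-0.01), reversed to a called 0.21, where the median of all genes also moved from -0.01 to 0.20; with a pseudocount of 1, 426 kept it, 9 lost and 3 gained it. Of 176 list results, medians had the same sign under the 3 scalings, 175 kept their call on the RPKM as deposited and 175 with no filter, and 13 kept it with an estimated correlation (163 lost, largest adjusted p = 0.736). Leaving out each library in turn for lists and genes named in the text, chosen after seeing the data, reversed 0 of them, ended the call of 7 of 176 lists and 2 of 212 gene values for at least 1 library, and moved 4 and 11 others over 1.5 times (fold or log2). No paired analysis was run because columns name groups and numbers and not animals, so fits with the animal as a block and with only the 2 intact limbs of each time were left out. The first 2 intact limbs of each bone in the labels belong to 4 h animals. Intact columns 1 and 2 stood above the others in Mt2 (392 and 428 against 21.5 to 48.5 scaled RPKM in femurs, 36.1 and 193 against 7.05 to 16.4 in ulnas). They also did in Odf3l2 (39.4 and 12.6 against 0.370 to 3.03 in femurs, 39.5 and 24.1 against 1.15 to 11.3 in ulnas). Car12 was alike (8.82 and 17.95 against 0.861 to 2.785 in femurs, 0.803 and 1.19 against 0.250 to 0.401 in ulnas). Whether column numbers follow the order of the labels was not tested. Depth from 8.12 to 30.8 M reads limits genes near 0.5 scaled RPKM.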

Other observations

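Lists in this part were fixed in advance and chosen for the text after the results were seen. Endothelial markers rose in 13 of 15 cases and fell in 1 at 5 d after stress fracture (median 0.40, adjusted p = 0.000587, and adjusted p = 0.229 with an estimated correlation), with Sox18, a vessel transcription factor, at 0.88 ± 0.14 and Vwf, von Willebrand factor, which platelets also carry, at -0.56 ± 0.12. At 14 d after full fracture they rose in 11 of 15 cases and fell in 1 (0.48, adjusted p = 0.023, and adjusted p = 0.555 with an estimated correlation), with Emcn, a marker of vessels coupled to bone formation, at 1.49 ± 0.12 and Vwf at -2.65 ± 0.14. Of 12 angiogenic factors 8 rose and 3 fell at 1 d after full fracture (0.91, adjusted p = 0.0193, and adjusted p = 0.347 with an estimated correlation), with Angpt2, which loosens vessels, at 1.97 ± 0.09 and Angpt1, which steadies them, at -1.20 ± 0.14. At 4 h after stress fracture 5 rose and 1 fell (7 and 2 adjusted over the list alone; 0.31, adjusted p = 0.0221, and adjusted p = 0.234 with an estimated correlation), with Angptl4 at 1.90 ± 0.43, and the call was lost without injured library 1 (adjusted p = 0.0712). Of 14 BMP and TGF-beta ligands and antagonists 9 rose and 1 fell at 5 d after stress fracture (0.48, adjusted p = 0.0189, and adjusted p = 0.229 with an estimated correlation), with Tgfb3 at 1.07 ± 0.13 and Grem1, a BMP antagonist, at -1.18 ± 0.20.

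Mesenchymal progenitor markers fell in 7 of 10 cases at 4 h after full fracture (median -1.003, adjusted p = 0.00535, and adjusted p = 0.461 with an estimated correlation), with Gli1, a hedgehog target of skeletal stem cells, at -1.50 ± 0.21 and Prrx1, a limb mesenchyme transcription factor, at -1.27 ± 0.12. At 5 d after stress fracture 6 rose and 1 fell (6 and 2 adjusted over the list alone; 0.80, adjusted p = 0.00426, and adjusted p = 0.121 with an estimated correlation), with Thy1 at 1.98 ± 0.15. Their difference between injuries was lower after full fracture in 6 of 10 cases at 4 h (-0.85, adjusted p = 0.00136, and adjusted p = 0.145 with an estimated correlation) and in 7 of 10 at 1 d (-0.69, adjusted p = 0.00152, and adjusted p = 0.169 with an estimated correlation). Glycolysis and hypoxia genes rose in 7 of 14 cases and fell in 1 at 4 h after full fracture (0.49, adjusted p = 0.0104, and adjusted p = 0.546 with an estimated correlation), with Slc2a1, a glucose transporter, at 3.20 ± 0.14. At 14 d 1 rose and 8 fell (2 and 9 adjusted over the list alone; -0.62, adjusted p = 0.00555, and adjusted p = 0.398 with an estimated correlation), with Egln3, an oxygen-sensing enzyme, at -2.50 ± 0.18. Interferon response genes rose in 9 of 14 cases at 4 h after full fracture (0.62, adjusted p = 0.0409, and adjusted p = 0.726 with an estimated correlation) and fell in 5 of 14 at 7 d after stress fracture (-0.35, adjusted p = 0.00908, and adjusted p = 0.387 with an estimated correlation), with Rsad2, an antiviral enzyme, at 1.31 ± 0.22 and -1.48 ± 0.26. The call at 4 h was lost without fractured library 2 (adjusted p = 0.123) and without intact library 3 (adjusted p = 0.0504).

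Of 23 fracture repair panel genes 17 rose and 2 fell at 14 d after full fracture (median 1.42, adjusted p = 5.84e-05, and adjusted p = 0.222 with an estimated correlation). At 5 d after stress fracture 19 rose and 1 fell (1.11, adjusted p = 3.14e-09, and adjusted p = 0.0771 with an estimated correlation), and at 7 d 19 rose, or 20 adjusted over the list alone (1.42, adjusted p = 5.79e-11, and adjusted p = 0.0796 with an estimated correlation). In intact ulnas 20 of the 23 were lower than in intact femurs, or 21 adjusted over the list alone (-1.17, adjusted p = 1.45e-09, and adjusted p = 0.0469 with an estimated correlation). Heat shock genes rose in 2 of 8 cases at 4 h after stress fracture, or 4 adjusted over the list alone (0.24, adjusted p = 0.00137, and adjusted p = 0.0769 with an estimated correlation), with Hspb1, a small chaperone, at 1.25 ± 0.23. Of 6 keratinocyte markers 1, Krt10, a skin keratin, passed the filter, too few for a test of the list, and it was at -1.08 ± 0.20 at 4 h after full fracture.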
